A study of Hygrophila difformis with 2 samples.

How the data were processed

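Shoots of water wisteria were sampled under 2 conditions, terrestrial and submerged, with 1 library of each, taken from the treatment label. Live protoplasts were loaded on the Chromium 3' platform with v3.1 chemistry and sequenced on an Illumina instrument, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 6.1.1 per the file headers, with no normalization. The values were checked to be whole numbers, and the library totals differ. The genome build, the annotation and any filter on cells are not given in the sources used here. The deposited count matrices hold 815 and 9361 barcodes, and the lowest barcode totals of 345 and 500 UMIs differ, so the barcodes of the libraries were not selected at one common minimum.

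The deposited feature lists hold 36099 identifiers, of which 0 are paired with a gene name, and no reference annotation was used here. The 15 gene lists and the cell type markers fixed before the data were examined could therefore not be matched. Under the rule fixed for that case, the first 2 genes of each direction are given by identifier. They were ranked, among genes with at least 50 CPM in the higher library, by the bound nearest to 1 of the interval of the ratio. Without gene models, paralogs, overlapping genes and antisense genes that share counts could not be set apart.

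Counts were summed over all deposited barcodes of a library and divided by the library total to give CPM. The ratio of submerged over terrestrial CPM has an exact conditional binomial 95% interval, a single level an exact Poisson interval and a share an exact binomial (Clopper-Pearson) interval. UMIs count molecules, and these intervals cover counting error only, not the variation between plants, protoplast preparations or libraries. A gene was tested for size when it had at least 20 CPM in the higher library, and was counted when the ratio reached 4-fold. Fewer than 3 counts were set to the floor of 3 counts. No p-value was computed, since cells are not replicates. The depth was uneven: 3 counts correspond to 3.24 CPM in the terrestrial library and 0.0829 CPM in the submerged library, so ratios of genes low in the terrestrial library are less precise. The 95% interval of the correlation comes from the standard deviation over 50 Poisson resamples of the counts.

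Cells with at least 200 detected genes were clustered jointly, which kept 815 terrestrial and 9310 submerged cells and left out 51 submerged barcodes. Counts were scaled to 10000 per cell, log-transformed and centred within each library. The 2000 most variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 0.5 were used, with scanpy 1.11.5, scikit-learn 1.9.0 and igraph 0.11.9 under Python 3.11.15. Numerical work used numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9. Doublets were kept. Scrublet, run on each library, marked 3 of 815 and 0 of 9361 barcodes, too few for a caller that has worked, so doublets remain untreated. Ambient RNA was not removed.

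The size rule was tested on counts simulated from the mean levels and totals of the 2 libraries, with 200 changed genes at each fold. For the submerged against the terrestrial library, 100% of genes changed 8-fold were recovered among 5819 tested genes and 100% of those changed 32-fold among 5706, with 0 and 3 unchanged genes called. Of genes changed 3-fold, 0% were called among 5938, and with no change 0 of 6004 genes were called. The simulated counts held counting noise only, and the changed genes were taken from those with a mean of at least 50 CPM. False calls from variation between real libraries were therefore not measured. The intervals held the true ratio for 94% to 98% of changed genes. Simulated cells of 3 profiles were recovered with an adjusted Rand index of 1 with centring and 0.919 without it. Both simulated libraries held the 3 profiles in equal shares, so centring of libraries with unlike mixes of cells was not tested.

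Alternatives listed with the design covered edgeR TMM factors (edgeR 4.0.16, R 4.3.3), totals without the 20 most abundant genes, the mean over cells, filters on cells and genes, equal weight per cluster, Scrublet calls left out, thinned counts, other pseudocounts and cluster settings. Alternatives added after the data were seen left out the 2 largest terrestrial barcodes, kept barcodes with at least 500 UMIs, left out barcodes dominated by Hdi000014, set the median ratio to 1, or rescaled the levels without filtering the genes again.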

Results

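Water wisteria (Hygrophila difformis) is an amphibious plant that grows on land and under water, and its leaves differ in form between these settings. Protoplasts, which are cells freed of their walls, were made from shoots of plants kept under terrestrial or submerged conditions. Their transcripts were read with droplet-based single-cell RNA sequencing of the 3' ends, in which each captured molecule carries a unique molecular identifier (UMI). The comparison asks how transcript levels and cell populations of the shoot differ between the 2 conditions. Each condition had 1 library, so no difference could be set against a spread between replicates and no p-value is given. All intervals cover counting error only.

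The terrestrial library held 815 barcodes and 927183 UMIs, and the submerged library held 9361 barcodes and 36176169 UMIs. The median barcode had 613 UMIs in the terrestrial library (quartiles 434 and 1035) and 3017 in the submerged library (quartiles 1446 and 5417). The smallest barcode had 345 UMIs in the terrestrial library and 500 in the submerged one, and 300 terrestrial barcodes (36.8%) lay under 500. In the terrestrial library the barcodes with the most UMIs held 73848 and 69056, against 10325 for the next, and together took 15.4% of the library. At least 1 UMI was found for 18576 of the 36099 annotated genes in the terrestrial library and for 26497 in the submerged library. With the submerged UMIs thinned at random to the terrestrial total, the submerged number was 18057. A count of 0 allowed up to 3 counts, which was 3.24 CPM (counts scaled to a common library total) in the terrestrial library and 0.0829 CPM in the submerged one.

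**Figure D1:**
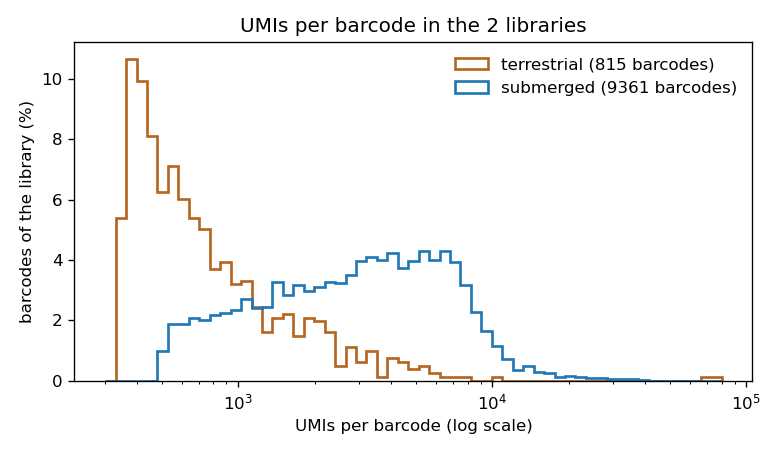
UMIs per barcode (x axis, log scale) against the percent of the library's barcodes in each bin (y axis), for the 815 terrestrial and 9361 submerged barcodes. The terrestrial barcodes had a median of 613 UMIs and the submerged barcodes a median of 3017, and 2 terrestrial barcodes stood apart near the upper end.

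The genes with the clearest difference toward the submerged library were Hdi016585 and Hdi000014. Hdi016585 had 12918 UMIs in the submerged library (357 CPM, exact Poisson 95% interval 351 to 363) and 0 in the terrestrial library, and was at least 110-fold higher against the floor of 3 counts. The exact binomial 95% interval of its ratio began at 89.7-fold. Hdi000014 stood at 32401 CPM in the submerged library (32342 to 32460) and at 324 CPM in the terrestrial library (288 to 362), a 100.1-fold difference (exact binomial 95% interval 89.4 to 113). The genes with the clearest difference toward the terrestrial library were Hdi015060 and Hdi005595. Hdi015060 had 4095 UMIs (4417 CPM, 4282 to 4554) in 378 terrestrial barcodes and 1 UMI in the submerged library. Its level was lower in the submerged library, with a counting interval of 28661-fold to 6312329-fold. Hdi005595 had 2238 UMIs (2414 CPM, 2315 to 2516) in the terrestrial library and 0 in the submerged library, and was at least 29107-fold lower there against the floor of 3 counts, with an exact binomial 95% interval that began at 23652-fold. Its terrestrial UMIs lay in 15 barcodes, 11 of which fell in cluster 16 of the joint clustering and held 2101 of them. The files list identifiers without gene names, so what these genes encode is not stated.

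Of 7181 genes with at least 20 CPM in either library, 580 were at least 4-fold higher and 1767 at least 4-fold lower in the submerged library. For 123 of the higher genes the terrestrial library was at the floor, and for 43 of the lower genes the submerged library was. The 580 higher genes took 3.76% of the terrestrial UMIs and 40.7% of the submerged UMIs, and the 1767 lower genes took 25.1% and 3.01%. The submerged library was concentrated in fewer genes. Its 10 most abundant genes took 26.7% of its UMIs, against 6.30% for the 10 most abundant genes of the terrestrial library. Across the tested genes, Pearson's r of log2(CPM + 1) between the libraries was 0.464 (0.461 to 0.468), with genes that are not independent replicates. Over all genes, with no minimum level, it was 0.813.

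**Figure D2:**
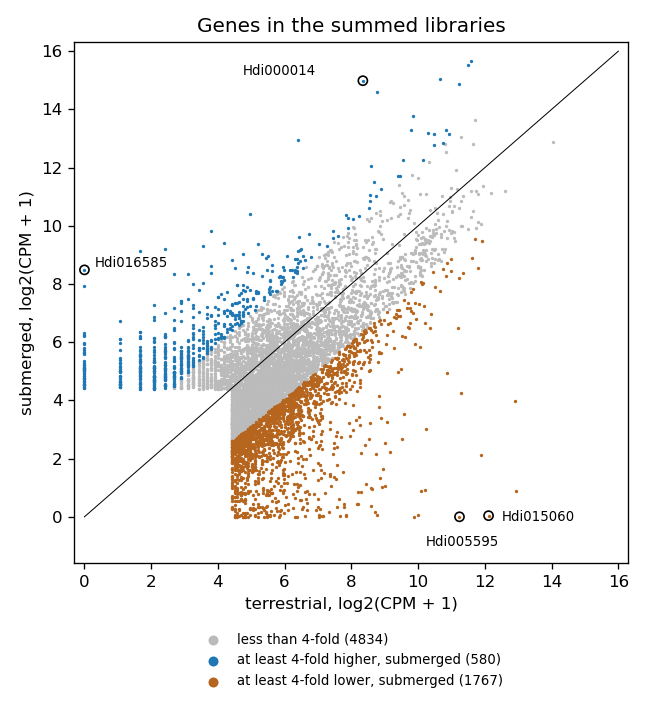
Level of each of the 7181 tested genes in the terrestrial library (x axis) and the submerged library (y axis), both as log2(CPM + 1), with the line of equal levels. The 580 genes at least 4-fold higher in the submerged library are blue, the 1767 at least 4-fold lower are brown, and the named genes are circled. Hdi016585 lies at 0 on the terrestrial axis, and Hdi015060 and Hdi005595 lie at the lower edge. The balance of higher and lower genes holds for the CPM scale only.

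The balance of directions depended on the scale. On the CPM scale 24.7% of the genes past 4-fold were higher in the submerged library, and the median log2 ratio of submerged over terrestrial levels was -1.10, with 71.4% of tested genes below 0. With trimmed-mean (TMM) factors on the same 7181 genes, 1160 were higher and 719 lower, 61.7% of the calls were higher, and the median was -0.08. With the minimum of 20 CPM also applied on the TMM scale, which left 6772 genes, 1386 were higher and 564 lower (71.1% higher) and the median was 0.30. With the 20 most abundant genes of either library left out of the totals, 825 of the same genes were higher and 1148 lower (41.8% higher), and 1034 and 1208 with the minimum applied again (46.1% higher). With the median ratio set to 1, 1223 were higher and 676 lower (64.4% higher). The median scale and the counts on the same 7181 genes were added after the data were seen. Each of these scales moves all log2 ratios upward by one amount. On the same 7181 genes, higher genes thus keep their call by construction and lower genes can only lose theirs. Where the minimum was applied again, genes not tested before could also be called in either direction. The direction of the typical gene is therefore not given by these counts, while the 4 named genes had ratios far beyond these shifts.

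Joint clustering of 815 terrestrial and 9310 submerged cells, with gene values centred within each library, gave 16 clusters. They are given by number, because no cell type marker could be matched to the identifiers. Cluster 6 held 526 terrestrial cells, 64.5% of that library (exact binomial 95% interval 61.1 to 67.8), and 33 submerged cells, 0.354% (0.244 to 0.497). Clusters 1, 2 and 3 held 67.3% of the submerged cells and 3 terrestrial cells. Clusters 14 and 16 held 72 and 18 terrestrial cells and 0 of 9310 submerged cells, which allows up to 3 cells, a share of 0.0322%. Clusters 5, 6, 7 and 12 held at least 20 cells of each library, and together took 86.9% of the terrestrial cells and 12.3% of the submerged cells. The overlap of the 2 distributions, the sum over clusters of the smaller share, was 14.3% (13.0 to 15.5). With submerged cells clustered alone and each terrestrial cell assigned to the best correlated of those clusters, the overlap was 41.9% and the largest terrestrial share 23.4%. With each cell thinned to 500 UMIs the overlap was 30.3%, and the cluster with the most terrestrial cells (66.6%) held 9.58% of the submerged cells. This thinning left out the 300 terrestrial cells with fewer UMIs and 0 submerged cells, so more than depth changed. With 1 library per condition, a cluster made mostly of 1 library may stand for that library in place of a cell type, and these shares also follow the unlike depth and barcode minimum of the libraries.

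**Figure D3:**
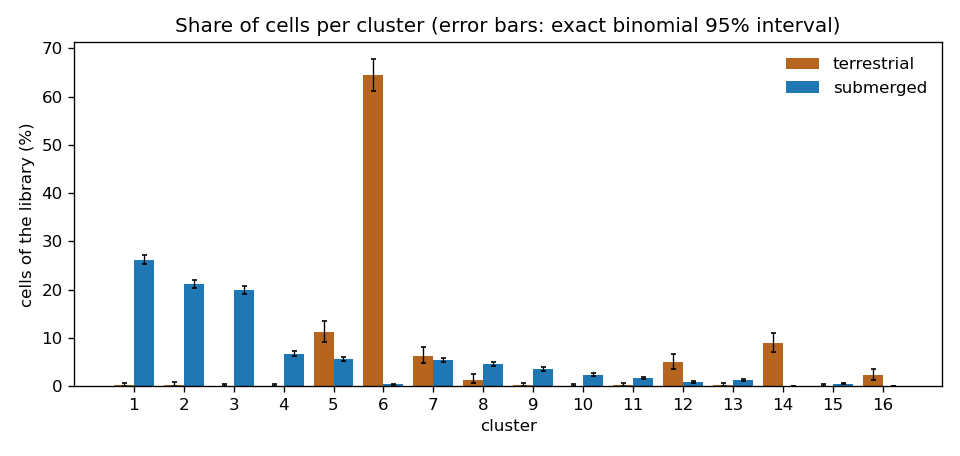
Percent of each library's cells (y axis) in each of the 16 joint clusters (x axis), with brown bars for the terrestrial and blue bars for the submerged library. Error bars are exact binomial 95% intervals for counting error only. Cluster 6 held 64.5% of terrestrial cells, and clusters 1, 2 and 3 held 67.3% of submerged cells.

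The named genes were followed within the 4 shared clusters. Hdi016585 had 0 UMIs in the terrestrial cells of each of them. In the submerged cells it stood at 461 CPM in cluster 5 (439 to 485), 894 CPM in cluster 6 (619 to 1249), 278 CPM in cluster 7 (258 to 299) and 118 CPM in cluster 12 (80.4 to 166). Hdi000014 was higher in the submerged cells of all 4. Its levels were 14579 against 255 CPM in cluster 5, 20604 against 417 CPM in cluster 6, 29378 against 706 CPM in cluster 7 and 867 CPM (760 to 985) against 131 CPM (86.5 to 191) in cluster 12, the smallest of these differences. The 2 largest terrestrial barcodes held 69.5% of the terrestrial UMIs of cluster 12, and without them its terrestrial level of Hdi000014 was 414 CPM (270 to 606). Hdi015060 stood at 7487 CPM in the terrestrial cells of cluster 6 (7244 to 7735), 4158 CPM in cluster 5 (3739 to 4611) and 1653 CPM in cluster 7 (1315 to 2052). It had 3 UMIs in those of cluster 12, where its level was at the floor. The submerged cells of these clusters held 0 UMIs of Hdi015060. Hdi005595 had 2 UMIs in the terrestrial cells of cluster 6 and 0 in those of clusters 5, 7 and 12, so its difference between the libraries was not detectable within the shared clusters. It stood at 44913 CPM in the terrestrial cells of cluster 16 (43013 to 46876). The ratio of the summed libraries for this gene thus rests mainly on cluster 16, which held 0 submerged cells.

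Of the 2347 genes past 4-fold, 1163 (49.6%) had a ratio in the same direction in all 4 shared clusters, 418 of the 580 higher genes and 745 of the 1767 lower genes. These calls came from all barcodes, and the 4 clusters held 86.9% of the terrestrial cells, so part of this agreement is built in. No such share was computed for genes that were not called. A gene with 0 counts on both sides of a cluster was not counted as going the same way. The terrestrial parts of clusters 5 and 7 held 86338 and 49608 UMIs, against 3421817 and 2660316 in the submerged parts. A lower gene with few counts could be missed there and fail, while a higher gene passed with few submerged UMIs. In cluster 6 the depths ran the other way, at 482336 against 38051. These shares thus also follow depth. The share was 73.6% over the 2 shared clusters with at least 50 cells of each library. Sets of higher and lower genes were also called again from barcodes outside each cluster, a comparison chosen after the data were seen, and read in genes whose mean level was worth at least 10 counts in the shallower part of the cluster. Genes called higher elsewhere were higher in the submerged cells for 103 of 103 in cluster 5, 97 of 128 in cluster 6, 61 of 62 in cluster 7 and 187 of 191 in cluster 12 (52 of 54 without the 2 largest terrestrial barcodes). Genes called lower elsewhere were lower for 201 of 202, 74 of 78, 100 of 100 and 354 of 397 in the same order (143 of 156 in cluster 12 without those barcodes). Genes not called elsewhere were higher in the submerged cells for 51.9%, 35.6%, 37.2% and 47.1% in that order. Ambient RNA was not removed and no background level was measured. Free RNA shared by the droplets of a library would carry calls from other barcodes into each cluster, so neither this comparison nor the levels by cluster show a change within the cells of a cluster.

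The higher set took at most 5.63% of the UMIs of any terrestrial cluster with at least 15 cells. In the submerged cells it took 52.2% in cluster 1 and 50.8% in cluster 2, but 12.3% in cluster 3 and 6.48% in cluster 12. The lower set took between 21.9% and 30.2% in the terrestrial clusters and between 1.44% and 10.9% in the submerged ones. These sets were chosen on the same libraries, so the gap between the libraries in sum is built in, and only its spread over clusters is a measurement.

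**Figure D4:**
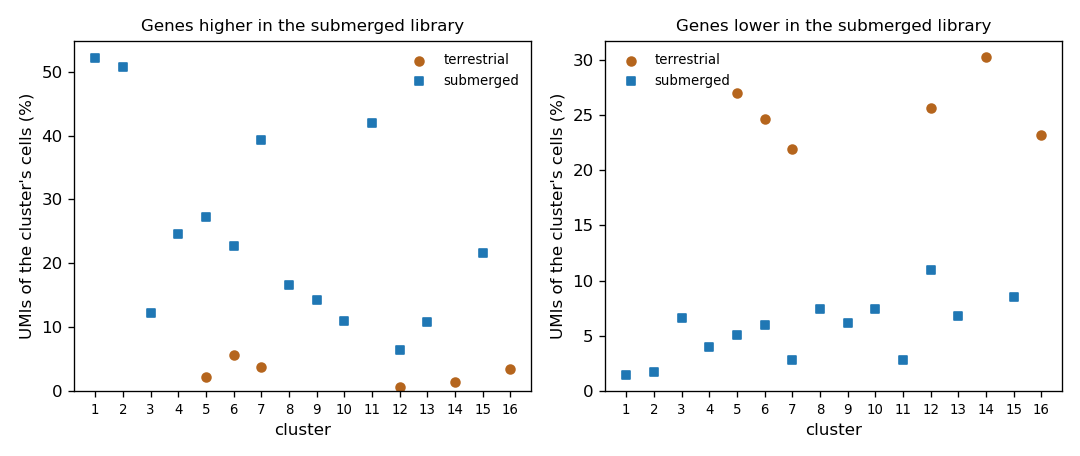
Percent of UMIs (y axis) from the 580 higher genes (left) and the 1767 lower genes (right) in each cluster (x axis), with brown circles for terrestrial and blue squares for submerged cells of clusters with at least 15 cells in the library. The higher set reached 52.2% in submerged cluster 1 and 6.48% in submerged cluster 12, and the lower set lay between 21.9% and 30.2% in the terrestrial clusters.

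The clusters were compared by their summed levels, with the submerged part of each thinned to 38051 UMIs in 100 random draws, a comparison chosen after the data were seen. Cells were joined in a cluster for similar expression, so a match of a terrestrial part with its own submerged part is largely built in. The terrestrial part of cluster 12 correlated with its own submerged part at r between 0.631 and 0.650 across genes, against at most 0.504 for any other. Without the 2 largest terrestrial barcodes, which left 62854 of its 205758 terrestrial UMIs, it was 0.545 to 0.562 against at most 0.463. The terrestrial parts of clusters 5 and 7 were closest to their own submerged parts in 99 and 94 of 100 draws. Over the draws, the range of that correlation overlapped the range for the next closest part. The terrestrial part of cluster 6 was closest to submerged cluster 15 in all 100 draws (0.577 to 0.586) and stood at 0.484 with its own. Terrestrial clusters 14 and 16 were closest to submerged cluster 3 in all 100 draws, at 0.473 to 0.497 and 0.441 to 0.459.

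Genes detected per cell were compared at a fixed depth. In cells thinned to 500 UMIs, the median was 369 genes in 515 terrestrial cells (quartiles 339 and 389) and 315 in 9361 submerged cells (quartiles 239 and 370), with 300 terrestrial cells and 0 submerged cells left out as too shallow. At 1000 UMIs the medians were 637 genes in 213 terrestrial cells and 512 in 7966 submerged cells, with 602 and 1395 cells left out. Without thinning the order was the opposite, at 424 genes in the terrestrial library and 1123 in the submerged library.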

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

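The limit of 30% of UMIs from Hdi000014, the set of genes at least 64-fold lower, and the tests on the largest barcodes, on the most abundant genes, on the variance of shallow barcodes and on the mix of genes between clusters were chosen after the results were seen.

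The 51 submerged barcodes with fewer than 200 detected genes, which entered no cluster, stood out because 58.0% of their UMIs (18924 of 32612, exact binomial 95% interval 57.5 to 58.6) came from Hdi000014, against 3.19% in the other submerged barcodes and 0.0324% in the terrestrial library. Every submerged barcode held at least 500 UMIs, so fewer than 200 genes selects barcodes whose UMIs lie on few genes. A high share of an abundant gene is therefore partly built in, and the terrestrial library had 0 such barcodes. Over the whole submerged library 123 barcodes (1.31%) drew more than 30% of their UMIs from this gene, up to 91.1%, while the highest terrestrial barcode reached 2.31%, and without those 123 its level was still 31178 CPM. Droplets holding free RNA only cannot be told apart from cells: among the 468 submerged barcodes with the fewest UMIs 46 drew more than 30%, while their median share of 0.546% decides nothing, since 123 barcodes are too few to move it. A single cluster of cells as their source stays open too, since of the 72 such barcodes that were clustered 56.9% lay in cluster 2 and 33.3% in cluster 1. No biological explanation was tested.

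A set of 102 genes had at least 50 CPM in the terrestrial library and was at least 64-fold lower in the submerged one, and 87 of them (85.3%) met the rule without the 2 largest terrestrial barcodes, which argues against those barcodes as the source. The set took 5.10% of terrestrial and 0.0141% of submerged UMIs, with 2.68% to 8.31% in the terrestrial clusters and at most 0.310% in any submerged cluster. Cells found only in the terrestrial library cannot be told apart from a wider source, since terrestrial cells of clusters made mostly of submerged cells (5, 7 and 12) held 61.3% of the share found in clusters made mostly of terrestrial cells, but no background was measured and RNA leaked from other cells would count there too. Free RNA from 1 source as the whole source in those cells stays open. The mix of the 40 of these genes with at least 15 counts there differed between clusters 5, 7 and 12 beyond counting error. Its chi-square was 72.9 per degree of freedom (39.5 without the 5 most deviant genes), where 1000 simulated draws from 1 mix reached at most 1.61. The clusters were formed on expression in the same cells, so part of this difference is built in. Draws from 1 mix take no account of that grouping and do not show how large that part is. UMIs of genes of the set rose 4.77-fold from the lower to the upper part of 180 of those 182 cells by UMI count. This decides little beside the 3.62-fold rise of all UMIs. Barcodes holding free RNA in place of a cell cannot be told apart from cells, because abundant genes in terrestrial barcodes under the median depth had a median variance of 1.96 times the Poisson value (quartiles 1.28 and 3.32), between the bounds set for either case, and the difference between terrestrial and submerged growth stays open as untested.

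Most tested genes were lower in the submerged library on the CPM scale, with a median log2 ratio of -1.10 over genes with at least 20 CPM. Unequal counting noise of the summed libraries is argued against, since the median was -1.06 with the submerged counts thinned to the terrestrial total. Random thinning leaves the expected CPM of each gene and the UMIs per barcode as they were, so other effects of depth stay open. The 20 most abundant genes are argued against as the whole source, since the median of the other tested genes was still -0.63 without them in the totals, but a wider shift in composition stays open because TMM factors gave -0.08 on the same 7181 genes. The mix of clusters cannot be told apart from a shift within cells, since the medians over abundant genes in the 4 shared clusters ran from -0.52 in cluster 7 to -0.0376 in cluster 5, between the bounds set for either case. A difference between the conditions stays open as untested.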

How the results depend on the processing

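Alternatives that leave out the largest or Hdi000014-dominated barcodes, keep barcodes with at least 500 UMIs, set the median ratio to 1 or rescale without filtering the genes again were chosen after the data were seen. The balance of higher and lower genes turned with the scale, and the order of the libraries in genes per cell turned without thinning. The median log2 ratio of -1.10 was -0.08 with TMM factors on the same 7181 genes and 0.30 on the 6772 that pass the minimum on that scale. The higher genes stayed within 1.5 times of 580 in 10 of 15 alternatives and the lower genes within 1.5 times of 1767 in 8 of 15. Higher and lower numbered 1386 and 564 with TMM factors (1160 and 719 on the same genes), 1223 and 676 with the median ratio set to 1, and 193 and 484 at a minimum of 100 CPM, where fewer genes are tested. Without the 20 most abundant genes in the totals, higher and lower numbered 1034 and 1208 among the 8156 genes that pass the minimum again. On the same 7181 genes they numbered 825 and 1148. The lower numbered 1050 with equal weight per cluster, which did not cover all clusters, and 8468 with no expression filter, where more genes are tested. Lower genes outnumbered higher ones in 12 of 15 alternatives, all but the TMM and median scales. The named genes had log2 ratios of 5.92 to 7.88 (Hdi016585), 5.44 to 7.74 (Hdi000014) and -15.94 to -9.18 (Hdi015060) over all 15. Hdi005595 lay between -15.08 and -9.54, except with equal weight per cluster, where both libraries are at the floor and no fold is given. That setting did not take in cluster 16, which held 2101 of the 2238 terrestrial UMIs of this gene and 0 submerged cells.

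The correlation of 0.464 was 0.583 with log2(CPM + 10), 0.404 as Spearman's rho and 0.813 with no filter. The median genes per cell at 500 UMIs, 369 terrestrial and 315 submerged, were 637 and 512 at 1000 UMIs and 424 and 1123 without thinning, which measures depth too. The overlap of cluster shares, 14.3%, was 19.6% without centring, 20.8% at resolution 0.25 and 12.7% at resolution 1. With 15 components it was 19.9%, and with 1000 variable genes 10.9%. It was 30.3% with cells thinned to 500 UMIs, which left out 300 terrestrial cells. Without Scrublet calls it was 16.7%, and with terrestrial cells assigned to submerged clusters 41.9%. The largest terrestrial share, 64.5%, was 60.1% without centring and 23.4% with that assignment, and it stayed within its interval in 7 of 9 alternatives. The share of genes with a common direction in the shared clusters, 49.6%, was 73.6% with at least 50 cells per library, where 2 clusters must agree in place of 4, and 42.2% at resolution 1. For the other shifts the cause was not tested. The Scrublet alternative removes 3 barcodes and so says little about doublets. The alternatives for gene lists were not run, since no list could be matched. No paired analysis was possible because each condition has 1 library. Depth limits the terrestrial side, where 3 counts are 3.24 CPM and a shared cluster held as few as 49608 UMIs.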

Other observations

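The tests on the largest barcodes, on genes held by few barcodes and on consecutive identifiers were chosen after the data were seen.

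The 2 largest terrestrial barcodes, with 7541 and 6686 detected genes, both fell in cluster 12. Across genes, their log levels correlated with each other at r = 0.802, with the rest of the terrestrial library at 0.523 and 0.547, and with the submerged library at 0.311 and 0.375. Without them the counts of genes past 4-fold were 555 higher and 1869 lower.

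Some terrestrial genes were held by very few barcodes. Of 3221 genes with at least 50 CPM in the terrestrial library, 44 had at least 90% of their UMIs in 10 barcodes, and 23 of these were at least 4-fold lower in the submerged library. Among 2047 such genes of the submerged library, 0 had that share in 115 barcodes, the same fraction of the library. The same 50 CPM stands for more UMIs in the deeper submerged library. The contrast was not made at equal depth, so part of it may follow from depth. The 2 largest barcodes took 15.4% of the terrestrial UMIs, against 0.209% in the submerged library, and the count was not repeated without them. The share of all 3221 genes that were 4-fold lower is not given, so 23 of 44 shows no excess. Hdi005595 is an example of a gene held by few barcodes, with 97.9% of its 2238 terrestrial UMIs in 10 barcodes.

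Hdi015060 was spread over many terrestrial barcodes but unevenly between clusters. It had 6.87 UMIs per barcode in cluster 6 (exact Poisson 95% interval 6.64 to 7.09), 3.95 in cluster 5 (3.55 to 4.38), 1.61 in cluster 7 (1.28 to 1.996) and 0.0750 in cluster 12 (0.0155 to 0.219), although cluster 12 had the deepest barcodes of these.

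A hypothesis was that genes past 4-fold sit side by side in the annotation, taking consecutive identifiers as neighbours. Of 1900 consecutive pairs of tested genes, 139 had both members past 4-fold in the same direction, 22 higher and 117 lower. Placing the calls at random among the tested genes 10000 times gave a mean of 127 pairs (SD 10.4) and a maximum of 165. The number lay within what chance placement gives, so the hypothesis has no support here, and whether consecutive identifiers are neighbours in the genome is not given in the sources used here.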
